A study of Mus musculus with 8 samples.

How the data were processed

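RNA of 8 samples in 4 groups of 2 was measured on mouse Affymetrix expression arrays: BCR-ABL1 bone marrow cells and splenic B cells stimulated with LPS and IL-4, each GFP-negative and GFP-positive, from mice carrying a GFP reporter for AID. The labels give total RNA extracted with a column kit, biotin labelling and the manufacturer's standard protocol, and name GCOS 1.3 for the processing. The deposited table holds signal intensities on a linear scale for 45101 probe sets. How the authors summarised probes and scaled the arrays, how the cells were purified before sorting, and whether replicates came from separate mice or cultures are not given in the sources used here. Trimmed mean intensities (2% trimmed) ran from 477 to 594, with group means of 590.0, 593 and 591 for the BCR-ABL1 GFP-negative, BCR-ABL1 GFP-positive and spleen GFP-positive arrays and 487 for the spleen GFP-negative arrays. With 2 arrays per group, the number of arrays limits precision.

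The tests, gene lists, alternatives and the rule for which genes may be named were chosen before the data were examined. Because the highest and lowest trimmed means differed by a ratio of 1.25, above the 10% allowed, arrays were quantile normalized. Values under 32 were then set to 32 and log2 transformed, so the scale was set before the floor, in the opposite order to the plan. Differences against a group at the floor in all its arrays are lower bounds, and medians of lists hold such genes at their bound. In a group with 1 array at the floor, the fold rests in part on that floor. An SD of 0 marks arrays at the floor or at the same rank after normalization. After 64 control probe sets were left out, 45037 remained, of which 34945 had 1 gene symbol, 932 several and 9160 none in the annotation used. Symbols were checked through 34754 matched Entrez gene IDs, which changed 0 of them. Probe sets with a mean log2 value under the 40th percentile (5.67, a signal of 51.0) were not tested, and each gene was represented by its brightest tested probe set with 1 symbol, which left 12223 genes, 5870 of them with several tested probe sets. The reporter gene and some other genes of the lists have no probe set of their own in the annotation used and are not reported here. No coordinates are given, since no file names a genome build.

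All 8 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend), with 1 mean per group and 4 residual degrees of freedom. The contrasts were the GFP effect in each source, their difference (the interaction), their mean, and the source effect (mean of both BCR-ABL1 groups minus mean of both spleen groups). p-values were adjusted by Benjamini-Hochberg over all genes of a contrast, and genes under 0.05 were called. The smallest two-sided p that exact permutation could give is 0.333 for 2 arrays against 2 and 0.0286 for 4 against 4, so the calls rest on the model. The 29 gene lists hold 548 genes, of which 456 were tested, 38 lay under the filter and 54 had no probe set of their own. They were tested with camera (preset correlation 0.01, adjusted over the lists of a contrast), with camera on an estimated correlation and with fry beside it, and members were also adjusted over the list alone. The lists cover class switch and mutation repair, cytidine deaminases, germinal centre, plasma, pre-B, pan-B and mature B cell genes, immunoglobulin constant genes, IL-4 and STAT6, NF-kB, interferon, STAT5, p53 and unfolded protein responses, MHC class II presentation, mitosis, DNA replication, checkpoint and homologous recombination, MYC and ribosome biogenesis, glycolysis and hypoxia, cholesterol synthesis, the BCL2 family, myeloid, T and NK, erythroid and megakaryocyte, dendritic, and stromal and endothelial cells, sex-linked genes, and stress and dissociation genes. Effects were compared across genes by Pearson and Spearman correlation and overlaps by Fisher tests.

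The alternatives were the deposited scale, a shift of each array to the same median, floors of 16 and 64, log2 of the value plus 32, no filter, a 60th percentile filter, eBayes without trend and with robust fitting, all probe sets, the mean of a gene's probe sets, array weights, the replicate number as a block (2 residual degrees of freedom), leaving out each array, the 4 arrays of a source alone and a 2-fold threshold. The 2 residual degrees of freedom of the block apply to the GFP contrasts, where it was the replicate number within each source. For the source effect, a term for the replicate number was added to the group means instead. Under alternatives that changed the scale, floor, filter or set of arrays normalized, a gene's brightest probe set was picked anew and could be another one. Normalizing within the 4 arrays of a source, the source effect within each fraction, and the deposited scale for lists and overlap were added after results were seen. Genes printed were a subset, picked after their values were seen, of those the rule allowed. Tlr7, Lpar1, Pygl, Thbd, Epcam, Maoa and the spleen values of genes shared with BCR-ABL1 cells were also picked after values were seen. The method was tested on simulated data built on the BCR-ABL1 contrast of 12223 genes with 200 changed: 38% of 1.5-fold changes, 80% of 2-fold and 97.5% of 4-fold changes were recovered, with false shares of 8.43%, 5.33% and 6.25%, and limma made 0 calls in an unchanged contrast. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.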

Results

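The series asked which transcripts differ between cells that express a GFP reporter for activation-induced cytidine deaminase (AID), the enzyme that starts class switching and somatic hypermutation, and cells that do not. The reporter was read in BCR-ABL1 bone marrow cells and in splenic B cells stimulated with LPS and IL-4, with 2 arrays for each of the 4 groups. Below, signals are means ± SD of 2 arrays, values in brackets are log2 fold changes ± standard error, and each gene said to rise or fall had an adjusted p under 0.05. The gene that drives the reporter is not reported here. Spearman correlations were taken over the deposited values of all 45037 probe sets that were not controls. The spleen GFP-positive arrays lay closer to the BCR-ABL1 arrays (mean 0.954) than to the spleen GFP-negative arrays (mean 0.846).

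**Figure D1:**
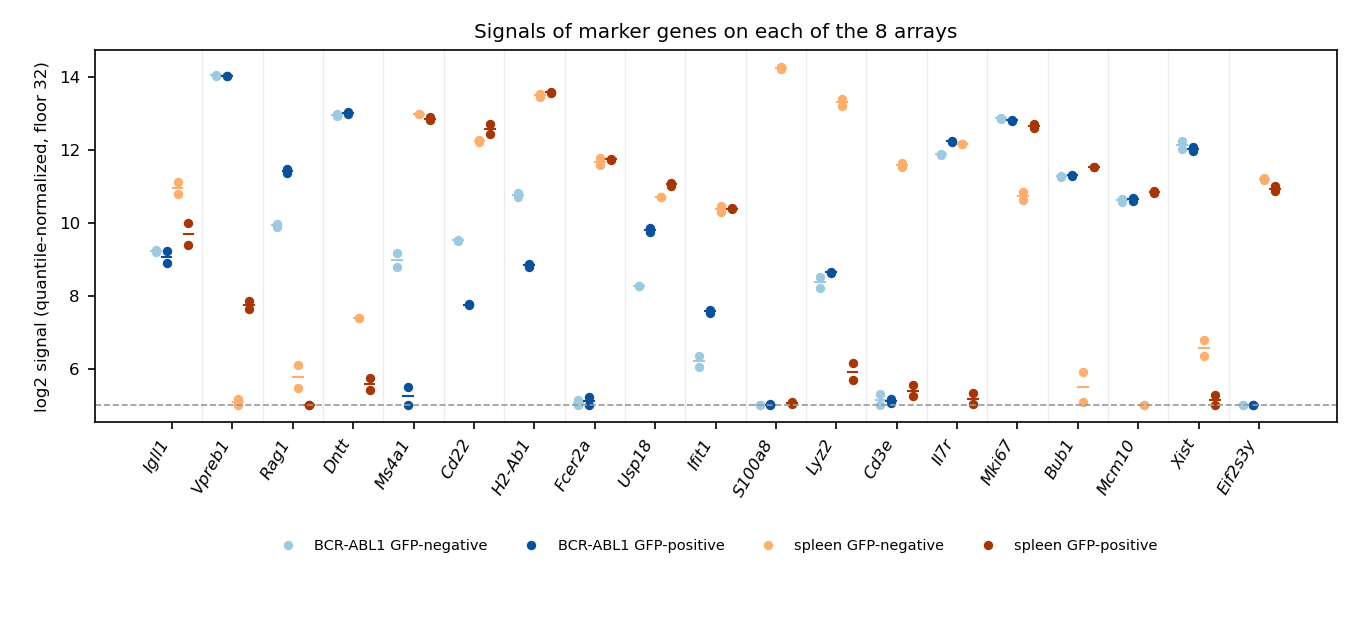
Signals of 19 genes in each of the 8 arrays on a log scale, 1 dot per array and a dash for the group mean. The dashed line marks the floor of 32, and dots on it are values at or under that floor.

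In BCR-ABL1 cells the GFP-positive fraction held less of several B cell surface transcripts (n = 2 arrays against 2). Ms4a1, which encodes CD20, fell from 509.7 ± 94.1 to 38.7 ± 9.47 (-3.73 ± 0.17), with 1 of the 2 GFP-positive arrays at the floor. Cd22, an inhibitory receptor of B cells, fell from 736 ± 11 to 215 ± 4.10 (-1.77 ± 0.092). Ly86, a partner of the RP105 receptor, fell from 1115 ± 46.2 to 187 ± 17.9 (-2.58 ± 0.078). Cd72 (-0.64 ± 0.054) and the quiescence factor Klf2 (-0.96 ± 0.12) fell as well. The class II chain H2-Ab1 fell from 1733 ± 84.9 to 457 ± 20.1 (-1.92 ± 0.058). Other genes of the class II pathway rose: H2-DMa (0.79 ± 0.074), H2-DMb2 (0.62 ± 0.040) and Cd74, the invariant chain, from 6608 ± 282 to 9416 ± 175 (0.51 ± 0.035). The gap junction gene Gja1 fell from 2165 ± 81.7 to 299 ± 31.4 (-2.86 ± 0.12), and the peptide transporter Slc15a2 (-2.86 ± 0.21), the phospholipase Pla2g7 (-2.83 ± 0.12) and Ehd2 (-2.51 ± 0.11) fell as well. The phosphatase Inppl1 (-2.45 ± 0.12) and the pre-B peptidase Enpep (-2.15 ± 0.15) fell too. Slamf7, a receptor found on plasma cells, fell (-1.75 ± 0.11), and so did Basp1 (-1.31 ± 0.098) and the early response gene Egr1 (-1.03 ± 0.064).

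The genes that rose in the BCR-ABL1 GFP-positive arrays included single members of the interferon and STAT5 lists tested below (n = 2 arrays against 2). Usp18, which limits interferon receptor signalling, rose from 309.7 ± 0.224 to 894 ± 50.6 (1.53 ± 0.079). Ifit1 (1.37 ± 0.13), Ifit3 (1.33 ± 0.096) and Oasl1 (1.26 ± 0.12) rose too, as did Oas3 (2.19 ± 0.17) and the GTPase Iigp1 (1.91 ± 0.15), which are not in the interferon list. Among STAT5 targets, the kinase Pim2 rose from 1161 ± 72.2 to 4296 ± 123 (1.89 ± 0.075) and the interleukin 2 receptor chain Il2ra from 1274 ± 44.8 to 3870.1 ± 9.34 (1.60 ± 0.071). Socs3 (0.77 ± 0.089) and Ccnd2 (0.37 ± 0.045) rose by less. Rag1 and Rag2, which cut antigen receptor genes, rose (1.5 ± 0.20 and 0.72 ± 0.11), as did Nt5e (1.54 ± 0.096). The surrogate light chain gene Vpreb1 stayed high in both fractions, at 16814 ± 259 and 16588 ± 0 (adjusted p = 1.00). Jchain, which joins IgM and IgA, rose from 245 ± 11 to 797 ± 88.2 (1.70 ± 0.082). Sparc rose from 81.8 ± 2.86 to 492 ± 72.1 (2.58 ± 0.33), and Mfap5 (2.35 ± 0.18), Col5a2 (2.04 ± 0.13) and Ccl25 (1.99 ± 0.17) rose too. The transcriptional regulator Tsc22d1 (1.96 ± 0.11) rose as well. Tnfaip3, an inhibitor of NF-kB, rose from 665 ± 18.0 to 1449 ± 4.77 (1.12 ± 0.065), with Gadd45b (0.67 ± 0.072) and the survival gene Bcl2 (0.58 ± 0.058).

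Single genes with smaller rises in BCR-ABL1 cells (n = 2 arrays against 2) were Foxo1 (0.29 ± 0.061), Prdm1 (0.71 ± 0.15), Irf4 (0.21 ± 0.035), Atm (0.42 ± 0.093), Cdkn1a (0.27 ± 0.051) and Apobec1 (0.28 ± 0.055). The glucose transporter Slc2a3 (-0.63 ± 0.080) and the glycolytic enzyme Tpi1 (-0.24 ± 0.037) fell. Bcl6 (0.35 ± 0.10, adjusted p = 0.113), Mki67 (-0.054 ± 0.071, adjusted p = 0.895), Brca1 (-0.15 ± 0.17, adjusted p = 0.864) and Ung (0.019 ± 0.15, adjusted p = 1.00) did not pass. Several of these calls were lost under some alternatives, mostly without 1 or more of the 4 BCR-ABL1 arrays. The largest adjusted p over all alternatives was 0.257 for Foxo1, 0.317 for Prdm1, 0.296 for Irf4, 0.272 for Atm, 0.239 for Cdkn1a and 0.201 for Apobec1. It was 0.125 for Tpi1, 0.0568 for Rag1, 0.133 for Rag2 and 0.296 for Gadd45b. With the 2-fold threshold set aside, 1 alternative each ended the calls for Sparc, Klf2 and Slc2a3. For Sparc it was the fit without a filter (largest adjusted p 0.0609). For Klf2 (0.0661) and Slc2a3 (0.0527) it was the fit of the 4 BCR-ABL1 arrays alone. With the mean of all probe sets of a gene, values were smaller for Ehd2 (-1.67), Nt5e (0.65), Sparc (1.32), Ccl25 (1.08), Tsc22d1 (1.27) and Atm (0.20). Oasl1 had 0.72 with a floor of 64, and Gadd45b 0.34 without GFP-negative replicate 1.

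Of 12223 genes, 656 passed in BCR-ABL1 cells (375 higher and 281 lower in GFP-positive arrays), 169 of them by at least 2-fold, and 1863 had an unadjusted p under 0.05. The count fell to 223 and 233 without GFP-negative replicates 1 and 2, to 221 and 206 without GFP-positive replicates 1 and 2, and stood at 997 and 978 without spleen GFP-negative replicates 1 and 2. These p-values measure the spread between these arrays alone, which may be technical, since nothing in the labels says that replicates came from separate animals or cultures.

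Gene lists were tested with camera, and in-list counts below adjust over the list alone. The interferon response list shifted up in BCR-ABL1 GFP-positive arrays (13 of 20 up, 16 up and 1 down in-list, median 0.60, adjusted p = 3.14e-17, and 0.0188 with an estimated correlation between genes). Its members Irf7, Stat2, Irf9, Ifih1 and Rsad2 rose along with Usp18, Ifit1, Ifit3 and Oasl1. The glycolysis and hypoxia list shifted down (5 of 20 down, 11 down in-list, median -0.18, adjusted p = 2.29e-09), a call lost with the estimate (estimated-correlation adjusted p = 0.116), as were the list calls that follow. Pan-B cell genes shifted down (1 up and 3 down of 18, 2 up and 5 down in-list, median -0.070, adjusted p = 0.00930; estimated-correlation adjusted p = 0.194). Mature B cell genes did too (2 up and 4 down of 18, 2 up and 5 down in-list, median -0.044, adjusted p = 0.0377; estimated-correlation adjusted p = 0.236). Cholesterol synthesis genes shifted up (0 of 15, the same in-list, median 0.16, adjusted p = 0.00108; estimated-correlation adjusted p = 0.194). So did the BCL2 family (2 of 12 up, the same in-list, median 0.20, adjusted p = 0.00273; estimated-correlation adjusted p = 0.193). The NF-kB response list was shifted up as well (4 of 23 up, the same in-list, median 0.069, adjusted p = 0.00930; estimated-correlation adjusted p = 0.236). The p53 response followed (2 of 21 up, the same in-list, median 0.11, adjusted p = 0.00930; estimated-correlation adjusted p = 0.341). The STAT5 response shifted up (4 of 16 up, the same in-list, median 0.036, adjusted p = 0.0274; estimated-correlation adjusted p = 0.232). Cytidine deaminases, of which 3 were tested, shifted up too (1 of 3 up, 2 up in-list, median 0.22, adjusted p = 0.0274; estimated-correlation adjusted p = 0.232).

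Lists of the cell cycle and of class switch repair did not pass in BCR-ABL1 cells by camera, and limma called 0 of their genes. These were mitosis (0 of 23, the same in-list, median 0.061, adjusted p = 0.235) and DNA replication (0 of 26, the same in-list, median -0.030, adjusted p = 0.191). Class switch and mutation repair was the other (0 of 29, the same in-list, median -0.032, adjusted p = 0.191). MHC class II presentation did not pass (4 up and 2 down of 13, 6 up and 3 down in-list, median 0.12, adjusted p = 0.305). Pre-B cell genes (3 up and 1 down of 23, 7 up and 2 down in-list, median 0.064, adjusted p = 0.0854) did not pass, but did without BCR-ABL1 GFP-negative replicate 1 (0.0295). Neither did plasma cell genes (4 up and 1 down of 15, 5 up and 4 down in-list, median 0, adjusted p = 0.814). Germinal centre B cell genes did not pass (1 up and 1 down of 16, 3 up and 2 down in-list, median 0.091, adjusted p = 0.671), nor did checkpoint and homologous recombination genes (1 of 22 up, the same in-list, median 0.012, adjusted p = 0.868). The erythroid and megakaryocyte list did not pass either (1 of 4 up, the same in-list, median -0.12, adjusted p = 0.835), nor did stromal and endothelial genes (1 of 6 up, the same in-list, median 0.087, adjusted p = 0.215). Of the 29 lists, 10 passed (7 up, 3 down), 1 with an estimated correlation and 13 with fry. Without spleen GFP-negative replicate 1 or 2 the count was 6. The calls lost without replicate 1 were STAT5 (adjusted p = 0.219), pan-B (0.139), mature B (0.139) and cytidine deaminases (0.0859), and without replicate 2 the same lists (0.226, 0.148, 0.148 and 0.131). Mature B was also lost without spleen GFP-positive replicate 1 (0.0509). Cytidine deaminases were lost without spleen GFP-positive replicate 2 (0.0598) and without BCR-ABL1 GFP-negative (0.0689) or GFP-positive replicate 2 (0.0638).

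**Figure D2:**
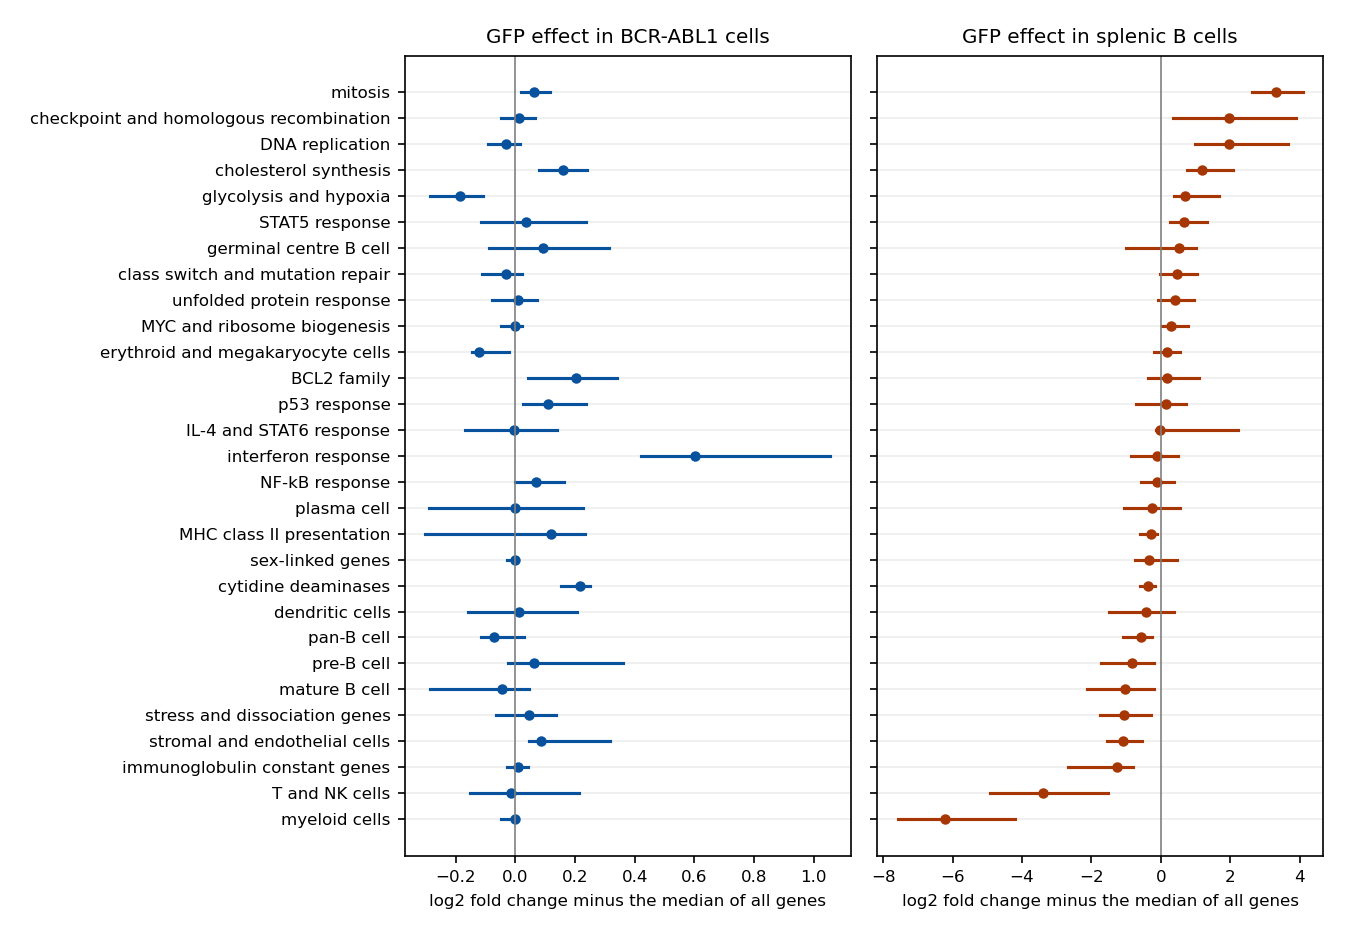
Median (dot) and range between the 25th and 75th percentiles (bar) of log2 fold changes in each gene list, minus the median of all genes, for the GFP effect in BCR-ABL1 cells (left) and splenic B cells (right), in order of the spleen medians. The axes differ in scale, and in the spleen the interferon, plasma cell, IL-4 and STAT6, and erythroid and megakaryocyte medians change sign on the deposited or the median-shifted scale. In BCR-ABL1 cells so do the T and NK, immunoglobulin constant, IL-4 and STAT6, MYC and ribosome biogenesis, and dendritic medians, all near 0, and the plasma cell, myeloid and sex-linked medians of 0 leave that value.

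In splenic B cells the GFP-negative arrays held high signals of genes of other blood cells that were near the floor in GFP-positive arrays (n = 2 arrays against 2). S100a8, a neutrophil protein, fell from 19166 ± 563 to 33.3 ± 0.757 (-9.17 ± 0.11), and S100a9 from 21955 ± 0 to 58.8 ± 2.52 (-8.55 ± 0.11). Lyz2 fell from 10069 ± 1032 to 61.4 ± 13.2 (-7.37 ± 0.17). The granule genes Camp (at least 260.0-fold lower) and Ngp (at least 209-fold) and the macrophage receptor Csf1r (at least 147-fold) were at the floor of 32 in both GFP-positive arrays. So was the T cell receptor component Cd3g (at least 78.3-fold lower), while Cd3e fell from 3068 ± 160.2 to 42.3 ± 6.04 (-6.19 ± 0.16). The NK cell receptor Klrd1 (-6.97 ± 0.14), the interleukin 7 receptor Il7r (-6.97 ± 0.10) and the regulator Klf4 (-3.29 ± 0.14) fell, and the integrin Itgax was at least 31.2-fold lower. The value of Csf1r was much smaller with a floor of 16 (-2.7) and without spleen GFP-negative replicate 1 (-2.82) or 2 (-2.66). A lower floor cannot shrink a fall to the floor, so -2.7 belongs to another probe set, picked anew in that setting. The values without an array may as well, and the bound holds for the probe set printed only.

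Genes of mitosis and DNA replication were higher in the spleen GFP-positive arrays (23 of 23 and 25 of 26, adjusted p = 0.0378 for both with an estimated correlation, n = 2 arrays against 2). Hmmr, a spindle protein, rose from 38.3 ± 8.85 to 3352 ± 75.7 (6.47 ± 0.14), and the checkpoint kinase Bub1 from 47.3 ± 18.4 to 2937 ± 9.69 (6.01 ± 0.22). Top2a (3.56 ± 0.049) and Mki67 (1.92 ± 0.071) rose by less. The replication factors Mcm10 (at least 57.4-fold) and Cdc6 (at least 53.7-fold) rose from the floor, and Tk1 rose as well (3.91 ± 0.089). Of the checkpoint and repair lists, whose calls were lost with an estimated correlation (adjusted p = 0.0671 and 0.114), Chek1 (5.77 ± 0.087), Brca1 (4.28 ± 0.17), Exo1 (4.41 ± 0.085) and Atm (0.80 ± 0.093) rose. The cell cycle inhibitor Cdkn1a, a p53 target, rose too (0.57 ± 0.051). Ung, which removes the uracil that AID makes, rose from 714 ± 190.1 to 2627 ± 148 (1.90 ± 0.15). Nfil3 (3.66 ± 0.11), Zbtb32 (3.81 ± 0.17), Batf (3.27 ± 0.18), Cish (3.28 ± 0.083), Il6 (4.34 ± 0.12), Socs3 (2.87 ± 0.089) and Il2ra (1.52 ± 0.071) rose. The enzyme genes that rose included Ido1 (at least 86.4-fold), Cth (at least 67.4-fold), Asns (3.54 ± 0.065), Fdps (2.05 ± 0.048), Lss (3.11 ± 0.085), Srm (1.98 ± 0.053) and Hk2 (1.89 ± 0.058). The interferon-induced GTPase genes Gbp2b (at least 48.5-fold) and Mx2 (2.63 ± 0.16) rose, whereas Ifit3 fell from 5596 ± 164 to 442 ± 18.6 (-3.66 ± 0.096). With the mean of all probe sets, values were smaller for Hmmr (3.57) and Top2a (1.45) and greater for Atm (1.68), Cdkn1a (1.1) and Il2ra (2.38). Hmmr had 4.13 with a floor of 16 and 4.12 to 4.13 without each BCR-ABL1 array. A lower floor cannot shrink a rise, so its value there belongs to another probe set, picked anew, and those without an array may too. Cdkn1a had 1.04 on the deposited scale and Mx2 1.72 with a floor of 64.

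Single genes of B cell fate and of antibody secretion went both ways in the spleen GFP-positive arrays (n = 2 arrays against 2). Whether other blood cells that may be in the GFP-negative fraction gave part of these signals was not tested. Bcl6, needed for germinal centres, fell from 5248 ± 233 to 2146 ± 169.8 (-1.29 ± 0.10), and Cxcr4 from 11880.5 ± 1147 to 2284 ± 133 (-2.38 ± 0.077). Icosl (-3.90 ± 0.089), the complement receptor Cr2 (-2.65 ± 0.12), Fcrla (-2.30 ± 0.11), Blk (-1.26 ± 0.044) and Ebf1 (-0.87 ± 0.053) fell, while Mef2b (3.76 ± 0.19) and Pax5 (1.40 ± 0.19) rose. The plasma cell list did not pass (5 up and 7 down of 15, the same in-list, median -0.064, adjusted p = 0.417), and its members Sdc1 (-2.64 ± 0.077), Jchain (-1.29 ± 0.082), Irf4 (-0.46 ± 0.035) and Xbp1 (-0.32 ± 0.065) were among the 7 that fell. The immunoglobulin genes Igha, from 10729 ± 510.4 to 728 ± 76.6 (-3.88 ± 0.18), and Ighg3 (-1.09 ± 0.10) fell too. Prdm1 did not pass (0.16 ± 0.15, adjusted p = 0.355), but did on the deposited scale (0.71). With the mean of all probe sets of a gene, Irf4 (0.22) and Ighg3 (0.29) changed sign and the Ebf1 call was lost (adjusted p 0.292, the largest over its alternatives). Xbp1 was lost on the deposited scale (0.101, its largest). Icosl was smaller with that mean (-2.37), and Ebf1 without each spleen array in turn (-0.38 to -0.24). After a median shift Pax5 had 0.76, Irf4 -0.87 and Xbp1 -0.63. For each of Top2a, Irf4, Ighg3 and Ebf1, 1 other tested probe set was called in the opposite direction.

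In the spleen 9426 of 12223 genes passed (5583 higher and 3843 lower), 4438 of them by at least 2-fold, with 9636 at an unadjusted p under 0.05. Higher genes made up 59.2% of the calls, against 69.3% on the deposited scale and 46.9% after a shift to equal medians. The median of all genes was 0.18, 0.40 and -0.081 on these 3 scales, so the lists below were tested relative to all other genes. The spleen GFP-negative arrays also had a lower trimmed mean than the GFP-positive ones (487 against 591) and higher 3' to 5' ratios of the controls Gapdh (1.91 against 1.44) and Actb (1.51 against 1.29).

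Myeloid cell genes were lower in the spleen GFP-positive arrays (19 of 19 down, the same in-list, median -6.05, adjusted p = 1.03e-11, and 0.0378 with an estimated correlation). T and NK cell genes were too (1 up and 14 down of 16, the same in-list, median -3.22, adjusted p = 7.66e-07; estimated-correlation adjusted p = 0.0671). All 19 and 16 lay above the filter value in the spleen GFP-negative arrays, but 7 and 10 in the GFP-positive arrays. Genes that passed the filter through the GFP-negative arrays alone could only be lower in GFP-positive arrays, so these counts and p-values overstate the evidence. Mitosis genes were higher (23 of 23 up, the same in-list, median 3.49, adjusted p = 3.73e-09, and 0.0378 with an estimated correlation). DNA replication genes were higher too (25 of 26 up, 25 up and 1 down in-list, median 2.14, adjusted p = 7.03e-08, and 0.0378 likewise). Checkpoint and homologous recombination genes shifted up (18 up and 2 down of 22, the same in-list, median 2.15, adjusted p = 0.000350; estimated-correlation adjusted p = 0.0671). Class switch and mutation repair genes did so by less (20 up and 5 down of 29, 20 up and 6 down in-list, median 0.65, adjusted p = 0.0308; estimated-correlation adjusted p = 0.114). Cholesterol synthesis shifted up (13 of 15 up, the same in-list, median 1.37, adjusted p = 0.000516; estimated-correlation adjusted p = 0.0965). Glycolysis and hypoxia genes did too (18 up and 2 down of 20, the same in-list, median 0.88, adjusted p = 0.000562; estimated-correlation adjusted p = 0.107). MYC and ribosome biogenesis did as well (19 of 23 up, 20 up in-list, median 0.48, adjusted p = 0.000516; estimated-correlation adjusted p = 0.0997). The unfolded protein response shifted up (16 up and 3 down of 23, 17 up and 3 down in-list, median 0.59, adjusted p = 0.00762; estimated-correlation adjusted p = 0.0965), and so did the STAT5 response (13 up and 3 down of 16, the same in-list, median 0.85, adjusted p = 0.0410; estimated-correlation adjusted p = 0.145).

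B cell lists shifted down in the spleen GFP-positive arrays. Pan-B genes were lower (2 up and 12 down of 18, the same in-list, median -0.40, adjusted p = 0.000726; estimated-correlation adjusted p = 0.0786). So were mature B genes (1 up and 11 down of 18, the same in-list, median -0.85, adjusted p = 0.00164; estimated-correlation adjusted p = 0.0965). Pre-B genes moved likewise (3 up and 15 down of 23, the same in-list, median -0.66, adjusted p = 0.00339; estimated-correlation adjusted p = 0.0965). Members that fell include Il7r (-6.97), named above with genes of other blood cells, and Nt5e (-3.09). Vpreb1 went the other way, at 32 and 36.1 in GFP-negative and 233 and 200 in GFP-positive arrays. A change of B cells and one of cell mixture cannot be told apart for the pan-B, mature B and pre-B lists. Stress and dissociation genes shifted down (3 up and 11 down of 16, the same in-list, median -0.88, adjusted p = 0.00953; estimated-correlation adjusted p = 0.131). Their member Klf4 (-3.29) was named above with genes of other blood cells, so cell mixture cannot be told apart for this list either. The interferon response did not pass (8 up and 6 down of 20, the same in-list, median 0.068, adjusted p = 0.746). Germinal centre B cell genes (9 up and 6 down of 16, the same in-list, median 0.72, adjusted p = 0.974) did not either. Nor did IL-4 and STAT6 targets (6 up and 3 down of 15, the same in-list, median 0.15, adjusted p = 0.355). On the deposited scale the counts were 12 up and 6 down for interferon (median 0.42) and 9 up and 1 down for IL-4 and STAT6 (0.58). Plasma cell genes, with 8 up and 5 down there (0.49), turned direction. Stromal and endothelial genes did not pass either (3 of 6 down, the same in-list, median -0.90, adjusted p = 0.0625), but did in 6 of the 8 fits without 1 array (0.0165 without spleen GFP-negative replicate 1, and 0.0349 to 0.0367). Immunoglobulin constant genes (3 of 3 down, the same in-list, median -1.09, adjusted p = 0.0588) passed without each BCR-ABL1 array in turn (0.0349 to 0.0451). Of the 29 lists 15 passed (9 up, 6 down), 3 with an estimated correlation and 26 with fry. Without spleen GFP-negative replicate 2 the STAT5 and the class switch and mutation repair calls were lost (adjusted p = 0.0701 and 0.0519).

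The GFP effect differed between the cell sources for many genes by the interaction term (n = 2 arrays in each of 4 groups, values are the BCR-ABL1 effect minus the spleen effect). Ifit3 rose in BCR-ABL1 cells and fell in the spleen (4.99 ± 0.14), and so did Nt5e (4.63 ± 0.14) and Jchain (2.98 ± 0.12). S100a8 (9.18 ± 0.16), S100a9 (8.31 ± 0.16), Camp (8.02 ± 0.18), Lyz1 (7.76 ± 0.44) and Klrd1 (7.74 ± 0.20) had the same sign. Ido1 (-6.43 ± 0.16), Hmmr (-6.32 ± 0.20), Cth (-6.23 ± 0.17), Bub1 (-6.0 ± 0.31), Cdc6 (-5.99 ± 0.12) and Mki67 (-1.97 ± 0.10) differed the other way, as did H2-Ab1 (-2.01 ± 0.082). Rag1 (2.28 ± 0.28) and Bcl6 (1.64 ± 0.14) had more positive effects in BCR-ABL1 cells. The values of Cth, Cdc6 and Rag1 rest on spleen groups at the floor and are bounds. Camp and Ido1 were at the floor in a spleen group and in all BCR-ABL1 arrays, so their BCR-ABL1 effect was not measured, and S100a8 was at the floor in 3 of the 4 BCR-ABL1 arrays. With the mean of all probe sets Nt5e had 1.38 and Hmmr -3.50. Hmmr had -4.0 to -3.90 without each BCR-ABL1 array, where another probe set may have been picked. In all, 8439 genes passed (3427 with the more positive effect in BCR-ABL1 cells, 5012 in the spleen), 4479 by at least 2-fold, with 8739 at an unadjusted p under 0.05. The share with the more positive BCR-ABL1 effect was 40.6%, against 30.2% on the deposited scale and 51.9% after a median shift. Of the 29 lists 17 passed (9 up, 8 down), 3 with an estimated correlation and 26 with fry.

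The mean GFP effect was tested over 4 arrays against 4 and follows whichever source moved more. Iigp1 (3.67 ± 0.10), the carbonic anhydrase Car13 (3.04 ± 0.069), the amino acid transporter Slc7a3 (2.80 ± 0.083), the ubiquitin ligase Siah2 (2.55 ± 0.085) and Hmmr (3.31 ± 0.098) had large positive mean effects, that of Hmmr through the spleen. Il2ra (1.56 ± 0.050), Socs3 (1.82 ± 0.063), Pim2 (1.35 ± 0.053), Usp18 (0.94 ± 0.056), Oasl1 (1.29 ± 0.085), Ifih1 (1.77 ± 0.12), Atm (0.61 ± 0.066), Cdkn1a (0.42 ± 0.036) and Prdm1 (0.43 ± 0.11) followed. Pla2g7 (-4.41 ± 0.087), the glycogen phosphorylase Pygl (-3.84 ± 0.095), Gja1 (-3.62 ± 0.084) and the receptor Lpar1 (-2.95 ± 0.097) had negative mean effects. So had Klf2 (-1.49 ± 0.083), Ccr7 (-0.95 ± 0.050), Sdc1 (-1.46 ± 0.055) and Basp1 (-1.18 ± 0.069). The values of Car13 and Gja1 rest on a spleen fraction at the floor and are bounds. With the mean of all probe sets Hmmr had 1.82, Atm 0.94 and Cdkn1a 0.72, and on the deposited scale Cdkn1a had 0.65 and Prdm1 0.74. For the mean, 8562 genes passed (5085 higher, 3477 lower), 1850 by at least 2-fold, with 8857 at an unadjusted p under 0.05. Higher genes made up 59.4%, against 70.3% on the deposited scale and 46.8% after a median shift. In 2732 of the 8562, the fractions did not overlap and differed in the same direction in both sources. Of the 29 lists 14 passed (8 up, 6 down), 3 with an estimated correlation and 25 with fry.

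Across all genes the BCR-ABL1 and spleen effects were nearly unrelated (Pearson r 0.0455, Spearman rho 0.0666). Of the 656 genes called in BCR-ABL1 cells, 519 were also called in the spleen, 250 of them (48.2%) in the same direction and 269 in the opposite one. Since 77.1% of all 12223 genes were called in the spleen, a large overlap would arise by chance. Genes higher in both, such as Mfap5 (2.10 ± 0.18 in the spleen), Tlr7 (1.27 ± 0.15 and 1.5 ± 0.15), Oasl1 and Il2ra, numbered 122, where 171 were expected by chance (Fisher test, adjusted p = 3.26e-07). Genes lower in both, such as Gja1, Pla2g7, Lpar1 (-2.14 ± 0.14 and -3.76 ± 0.14), Pygl and Thbd (-1.62 ± 0.23 in BCR-ABL1 cells, at least 15.1-fold lower in the spleen), numbered 128 against 88.3 (adjusted p = 7.99e-07). Genes higher in BCR-ABL1 and lower in spleen GFP-positive arrays, such as Slfn1 (1.95 ± 0.15 and -4.16 ± 0.15), Nt5e, Ifit3 and Epcam (1.19 ± 0.11 and -3.15 ± 0.11), numbered 181 against 118 (adjusted p = 2.85e-11). The reverse, with Inppl1 (2.27 ± 0.12 in the spleen), Eps8 (-2.32 ± 0.31 and 2.17 ± 0.31) and Maoa (-2.11 ± 0.15 and 3.10 ± 0.15), held 88 against 128 (adjusted p = 7.99e-07). The same spleen contrast holds the falls of myeloid and of T and NK genes (medians -6.05 and -3.22). Genes are not independent replicates, so these p-values overstate the evidence. The calls of Thbd and Eps8 in BCR-ABL1 cells were lost under some alternatives (largest adjusted p 0.0728 for both), including without single BCR-ABL1 arrays. Another Nt5e probe set was called in the opposite direction in the spleen, where the mean of its probe sets was -0.73. That mean was -1.36 for Lpar1 in BCR-ABL1 cells and 1.27 for Mfap5 in the spleen, and a floor of 64 gave 1.11 for Slfn1 in BCR-ABL1 cells. The number called in both was 168 and 173 without BCR-ABL1 GFP-negative replicates 1 and 2, 161 and 156 without BCR-ABL1 GFP-positive replicates 1 and 2, and 796 and 781 without spleen GFP-negative replicates 1 and 2.

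**Figure D3:**
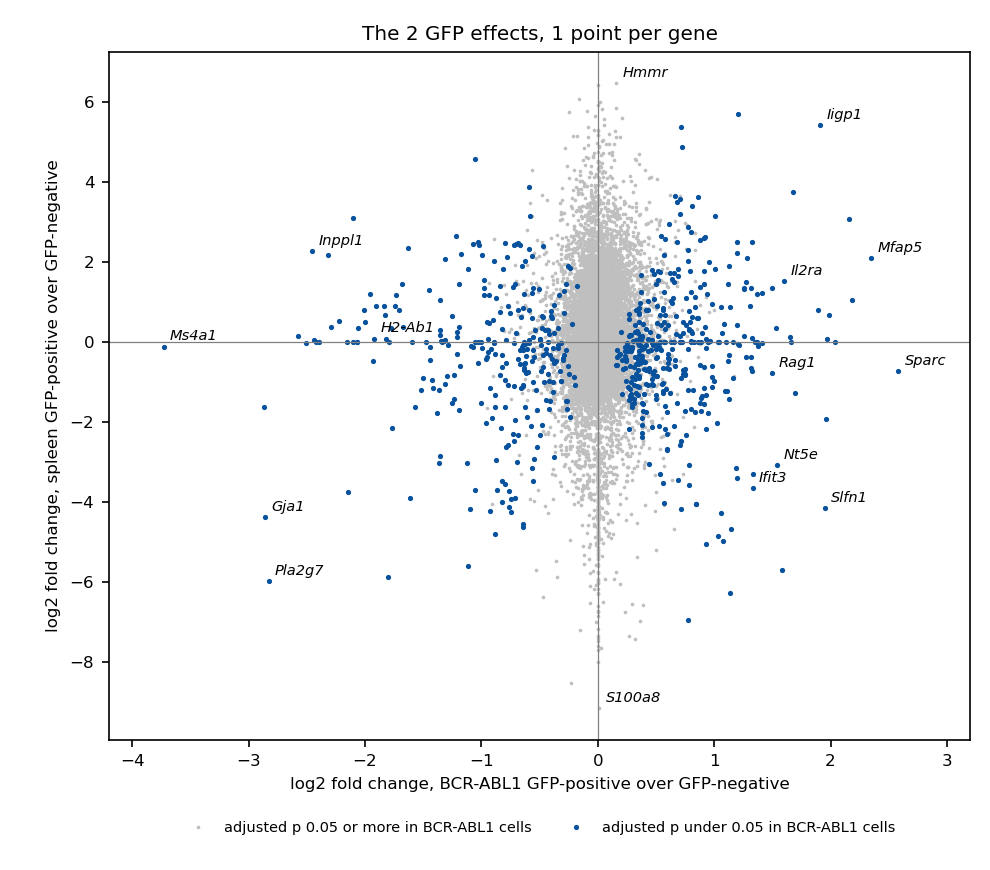
Log2 fold change of each of 12223 genes in BCR-ABL1 cells (horizontal) and in splenic B cells (vertical), with genes called in BCR-ABL1 cells in blue. Points in line at a vertical value of 0 are genes at the floor of 32 in all 4 spleen arrays.

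Between the sources, BCR-ABL1 cells held more of 19 of 23 pre-B genes (adjusted p = 2.03e-05, n = 4 arrays against 4, each source with both fractions). Vpreb1 stood at 16814 ± 259 and 16588 ± 0 against 34.0 ± 2.88 and 216 ± 23.1 in the spleen fractions, GFP-negative first (7.61 ± 0.068). Igll1, which encodes its partner, was lower by its brightest probe set (-1.18 ± 0.15), but 1 other tested probe set was called in the opposite direction. The mean of its probe sets was higher (2.80), as was the value without each spleen array in turn (6.68 to 6.95). The signals of the brightest probe set cannot give the latter, which belongs to another probe set, picked anew. Dntt (6.49 ± 0.081), Rag1 (5.28 ± 0.14), Bst1 (4.13 ± 0.057), Vpreb3 (3.13 ± 0.048), the myosin light chain Myl10 (7.71 ± 0.052) and Mycn (7.59 ± 0.086) were higher too. So were Tgfb3 (6.67 ± 0.080), Ccn3 (at least 134-fold), Tmem119 (6.77 ± 0.080), the STAT5 targets Socs2 (2.96 ± 0.047), Ccnd3 (2.72 ± 0.041) and Cish (2.93 ± 0.058), and Cdkn1a (2.22 ± 0.036). The values of Rag1, Tgfb3 and Tmem119 rest in part on a spleen fraction at the floor. Cish had 1.19 among GFP-positive and 4.67 among GFP-negative arrays. Mki67 was higher over both fractions (1.14 ± 0.050), but the call was lost among GFP-positive arrays (0.104, the largest adjusted p over its alternatives). Pax5 was higher (1.08 ± 0.13, and 0.56 with the mean of its probe sets) with overlapping arrays, and Ebf1 did not pass (0.024 ± 0.037, adjusted p = 0.582) and ranged from -0.40 to 1.12 over its alternatives, passing without each of the 4 spleen arrays in turn.

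Of the mature B cell list, 17 of 18 genes were higher in the spleen (adjusted p = 8.50e-09, n = 4 arrays against 4). Cd83 was at least 329-fold lower in BCR-ABL1 cells, Gpr183 at least 86.0-fold, Cd86 at least 84.0-fold, Acod1 at least 101-fold and Ccl5 at least 91.4-fold. Class II genes H2-Aa (-8.14 ± 0.14), H2-Eb1 (-7.64 ± 0.073) and H2-Ab1 (-3.73 ± 0.041), Fcer2a, which encodes CD23 (-6.61 ± 0.092), the chemokine receptor Ccr6 (-5.67 ± 0.095) and the protease Ctsh (-6.81 ± 0.11) were lower too. The values of H2-Aa and, below, Igkv9-120 rest in part on a BCR-ABL1 fraction at the floor. NF-kB and interferon targets were lower: Traf1 (-5.54 ± 0.079), Bcl3 (-4.63 ± 0.072), Rsad2 (-5.02 ± 0.077) and Cxcl10 (-5.19 ± 0.090). Egr2, of the stress and dissociation list, was lower too (-4.91 ± 0.11). Immunoglobulin genes Ighg3 (-5.86 ± 0.073), Igha (-5.22 ± 0.13), Jchain (-4.12 ± 0.058), Igkv9-120 (-7.48 ± 0.078) and Iglv1 (-6.73 ± 0.073) were lower, as were Bcl6 (-4.32 ± 0.071) and Prdm1 (-2.33 ± 0.11). The size of the Igkv9-120 difference depends on the probe set: it was -3.90 with the mean of its probe sets. It was -0.32 with a floor of 16 and -0.36 to -0.29 without each spleen array in turn. A lower floor cannot shrink it, so -0.32 belongs to another probe set, picked anew, and the values without an array lie near that. Among GFP-positive arrays Igha had -3.31 and Jchain -2.63. Sex-linked genes went with the source: Xist, expressed from the inactive X, stood at 4517 ± 502 and 4157 ± 263 in BCR-ABL1 fractions against 96.4 ± 20.5 and 35.4 ± 4.80 (6.22 ± 0.12). The Y-linked genes Eif2s3y (at least 67.1-fold) and Kdm5d (at least 9.97-fold) were at the floor in BCR-ABL1 cells, as was Uty (-1.36 ± 0.097, and -2.73 among GFP-positive arrays), which was also at the floor in the spleen GFP-negative arrays. Expression of sex-linked genes was therefore confounded with the cell source. So was stimulation, since LPS and IL-4 are named in the spleen labels only. The source differences above cannot be told apart from an effect of stimulation.

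In all, 9070 genes passed between the sources (5160 higher in BCR-ABL1 cells, 3910 lower), 2999 by at least 2-fold, with 9305 at an unadjusted p under 0.05. Higher genes made up 56.9%, against 66.3% on the deposited scale and 41.7% after a median shift. In 4473 of the 9070, the arrays of the 2 sources did not overlap. Among GFP-positive arrays alone 6149 genes passed (3029 higher, 3120 lower), and among GFP-negative arrays 9589 (5582 higher, 4007 lower).

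Interferon response genes were lower in BCR-ABL1 cells (20 of 20 down, the same in-list, median -2.0, adjusted p = 3.64e-10). So were NF-kB response genes (2 up and 21 down of 23, the same in-list, median -2.24, adjusted p = 4.88e-10). Mature B cell genes were lower (1 up and 17 down of 18, the same in-list, median -2.29, adjusted p = 8.50e-09). MHC class II genes were lower (1 up and 12 down of 13, the same in-list, median -1.26, adjusted p = 4.58e-07). Pre-B cell (19 up and 4 down of 23, the same in-list, median 3.19, adjusted p = 2.03e-05) and STAT5 response genes (16 of 16 up, the same in-list, median 1.39, adjusted p = 8.12e-06) were higher. These 6 calls were kept with an estimated correlation (adjusted p = 0.0256 for each). Plasma cell genes were lower (2 up and 12 down of 15, the same in-list, median -0.88, adjusted p = 0.000253, and 0.0460 with the estimate). Stress and dissociation genes were lower (1 up and 13 down of 16, the same in-list, median -1.56, adjusted p = 3.52e-05, and 0.0460 with the estimate), within GFP-positive (median -0.98) and GFP-negative arrays (-1.92) alike. Immunoglobulin constant genes (3 of 3 down, the same in-list, median -5.22, adjusted p = 0.00296; estimated-correlation adjusted p = 0.0618) were lower. Germinal centre genes were lower (3 up and 9 down of 16, the same in-list, median -0.88, adjusted p = 0.00545; estimated-correlation adjusted p = 0.0618). IL-4 and STAT6 targets were lower too (3 up and 11 down of 15, the same in-list, median -1.17, adjusted p = 0.00115; estimated-correlation adjusted p = 0.0519). Dendritic cell genes were as well (7 of 8 down, the same in-list, median -1.55, adjusted p = 0.000542; estimated-correlation adjusted p = 0.0965), but they did not pass among GFP-positive arrays (1 up and 4 down, adjusted p = 0.109, against 8 down and 0.000867 among GFP-negative arrays). The sex-linked list did not pass (1 up and 3 down of 4, the same in-list, median -2.34, adjusted p = 0.128). Mitosis genes had a median of 3.59 among GFP-negative arrays and 0.018 among GFP-positive arrays, and DNA replication genes 2.17 and 0.039. Myeloid genes had -6.08 and -0.043, whereas pre-B genes were higher within both fractions (2.79 and 3.59) and interferon genes lower within both (-2.34 and -1.87). Of the 29 lists 20 passed (8 up, 12 down), 11 with an estimated correlation and 27 with fry. Stimulation with LPS and IL-4, named for the spleen only, cannot be told apart from the source in these lists.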

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

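The items below stood out because the interaction term, planned from the start, passed for them, or because a signal appeared among probe sets that the comparisons by gene did not use. All 10 tests of explanations in this part were chosen after the results were seen.

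The GFP effect differed between the cell sources for 8439 genes (n = 2 arrays in each of 4 groups, values are BCR-ABL1 minus spleen, log2). The named genes with a more positive effect in BCR-ABL1 cells were S100a8 (9.18), S100a9 (8.31), Camp (8.02), Lyz1 (7.76), Klrd1 (7.74), Ifit3 (4.99), Nt5e (4.63), Jchain (2.98), Rag1 (2.28, a bound) and Bcl6 (1.64). Those with a more positive effect in the spleen were Ido1 (-6.43), Hmmr (-6.32), Cth (-6.23, a bound), Bub1 (-6.0), Cdc6 (-5.99, a bound), H2-Ab1 (-2.01) and Mki67 (-1.97). Camp and Ido1 had no measured effect in BCR-ABL1 cells, where all arrays were at the floor. S100a8 was at or near the floor in all BCR-ABL1 arrays, so its value reflects the spleen.

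The interaction passed for 17 lists with camera, given here as median and adjusted p with an estimated correlation. More positive in BCR-ABL1 cells were myeloid (6.05, 0.0331), T and NK (3.32, 0.0630), stromal and endothelial (1.49, 0.384), immunoglobulin constant (1.1, 0.176), pre-B (0.81, 0.0847), stress and dissociation (0.78, 0.187), mature B (0.74, 0.109), interferon (0.47, 0.0847) and pan-B genes (0.33, 0.0847). More positive in the spleen were mitosis (-3.54, 0.0331), DNA replication (-2.23, 0.0331), checkpoint and homologous recombination (-2.11, 0.0630), cholesterol synthesis (-1.17, 0.0847), glycolysis and hypoxia (-1.05, 0.0847), class switch and mutation repair (-0.82, 0.0847), MYC and ribosome biogenesis (-0.46, 0.0863) and the unfolded protein response (-0.44, 0.0847). Leaving out arrays in turn ended some calls: immunoglobulin constant genes without spleen GFP-negative replicate 1 (adjusted p = 0.0739) or 2 (0.0639) or GFP-positive replicate 1 (0.0653) or 2 (0.0538), stromal and endothelial genes without spleen GFP-positive replicate 1 (0.0653), and stress and dissociation genes without spleen GFP-positive replicate 2 (0.0538). Of these lists, only the myeloid, mitosis and DNA replication calls were kept with the estimate. The myeloid difference largely restates the spleen fall (median -6.05). Of 19 myeloid genes tested, 7 lay above the filter value in BCR-ABL1 GFP-negative and 6 in GFP-positive arrays, against 19 in spleen GFP-negative arrays. For genes that passed the filter through the spleen GFP-negative arrays alone, the sign was set by the filter. Of 4451 tested probe sets with no symbol or several, which the comparisons by gene left out, 66 passed in BCR-ABL1 cells and 3611 in the spleen.

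The first pattern weighed was the high signal of myeloid, T and NK cell genes in the spleen GFP-negative arrays. As a hypothesis, such cells in the GFP-negative fraction may be its source: both lists were higher there, T and NK genes by the smaller median (-3.22), and S100a8 (19166), Lyz2 (10069) and Cd3e (3068) reached high signals. Sorting GFP-negative cells would not remove cells that lack the reporter. Of the 19 myeloid and 16 T and NK genes, 7 and 10 lay above the filter value in the spleen GFP-positive arrays too, and 1 of the T and NK genes is in another list. For genes that passed the filter through the GFP-negative arrays alone, the direction was set by the filter. The tables argue against scaling, since the median over both lists stayed at -4.01 or below on 3 scales. They argue against RNA degradation too: the 3' to 5' ratio of a housekeeping control was higher in the GFP-negative arrays (log2 difference -0.40), the arrays where these genes were higher. A change of such genes within B cells was not tested and stays open.

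The second pattern was the higher signal of mitosis and DNA replication genes in the spleen GFP-positive arrays. Dilution of B cells by others in the GFP-negative fraction would raise pan-B genes in GFP-positive arrays alike, if their level per B cell stayed the same. The 75th percentile of pan-B genes was -0.075 while the 25th percentile of the cycle genes was 1.92. That level was not tested, and single pan-B genes moved (Blk, Fcrla and Ebf1 fell, Pax5 rose). A share of dilution in the difference therefore stays open. The tables argue against scaling, which left the cycle median at 3.27 or above on 3 scales. A link of the reporter with cycling in both sources found no support, as the same genes had a median of 0.015 in BCR-ABL1 cells, where mitosis genes were high in both fractions. RNA degradation goes in the direction of this pattern, since the 3' to 5' ratio of a control was higher in the GFP-negative arrays (log2 difference -0.40). That is less than the 25th percentile of the cycle genes, but a pair of control transcripts does not give the loss of others, so degradation and a change of these genes cannot be told apart here. As a hypothesis, stimulated spleen cells that turned the reporter on may divide more than those that did not, which these arrays cannot separate from a difference in activation.

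The third pattern was the rise of interferon response genes in the BCR-ABL1 GFP-positive arrays, with a median of 0.60. A single array was not its source: without each of the 4 BCR-ABL1 arrays in turn, the largest adjusted p of the list was 2.89e-16. Scaling was tested first and left the median between 0.60 and 0.62, and the test of stromal cells took its place. In it, 4 transcripts abundant in stromal cells differed by 0.12 at most, a pair of them at the floor in both fractions. Sparc rose by 2.58, and Mfap5 (2.35) and Col5a2 (2.04), which were not among the 4, rose as well. Stromal cells in the GFP-positive fraction therefore stay open. For myeloid, T or NK cells, the median of both lists (0) and the highest of 6 abundant transcripts (0.27, Lyz2, standard error 0.17) were tried first, and the last form compared the median of the 6, which was 0 with an SD of 0.16, with the 25th percentile of the interferon genes, 0.42. As a hypothesis, the response may belong to the reporter-positive BCR-ABL1 cells themselves, and whether AID or signals shared with it cause it was not tested.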

How the results depend on the processing

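The tests chosen after the results were seen in this part are normalization within the 4 arrays of a source, the source effect within each fraction, and the deposited scale for lists and overlap. Of 218 gene results, 211 were called, of which 189 kept their call in every alternative other than the 2-fold threshold and 22 lost it or changed sign in at least 1, and 7 were not called. Over all alternatives of these genes, 5003 outcomes were the same, 109 weaker, 10 stronger and 9 of opposite sign. For lists these were 1732, 88, 63 and 2. Counts in BCR-ABL1 cells depended most on settings: 656 became 1593 with array weights, 2015 when the 4 arrays were normalized and fitted alone, and 206 to 997 when arrays were left out in turn, with 206 to 233 without any 1 BCR-ABL1 array, and 997 and 978 without spleen GFP-negative replicates 1 and 2. The planned fit of the 4 BCR-ABL1 arrays alone, with normalization and filter taken over all arrays, gave 484. The rise to 2015 therefore came with the new normalization and filter. The spleen GFP-negative replicates were the least alike (Spearman correlation 0.984, against 0.994 to 0.996 within the other groups), while the fit gives all groups 1 shared spread. Whether this caused the changes in count was not tested. Lists called there ranged from 1 (estimated correlation) to 13 (fry), and from 6 (without spleen GFP-negative replicate 1 or 2) to 11 when arrays were left out. With arrays left out, genes called in both sources ranged from 156 (without BCR-ABL1 GFP-positive replicate 2) to 796 (without spleen GFP-negative replicate 1). Testing all probe sets gave 21129 calls in the spleen, 18864 for the difference, 19077 for the mean and 19996 for the source, since more units were tested. The 2-fold threshold left 169 (BCR-ABL1), 4438 (spleen), 4479 (difference), 1850 (mean) and 2999 (source). With an estimated correlation, lists called numbered 1, 3, 3, 3 and 11 in that order, and with fry 26 for the spleen, 26 for the difference and 25 for the mean. With the replicate number as a block, counts were 715, 9766, 8835, 8975 and 9500, and lists 9, 14, 16, 14 and 20. Residual correlations of equally numbered arrays were 0.129 in BCR-ABL1 cells and 0.274 in the spleen, against 0.160 to 0.286 between sources, so all 6 pairs of groups deviated together to some degree. A batch shared by equally numbered arrays of all groups would give this too, and with 2 arrays per group the pairing is left open. The list calls lost with the block were STAT5 in BCR-ABL1 cells (adjusted p = 0.0519) and in the spleen (0.0509), and immunoglobulin constant genes for the difference (0.062). Signs reversed for Igll1 between the sources (2.80 with the mean of probe sets, 6.68 to 6.95 without each spleen array in turn, against -1.27 to -1.10 without each BCR-ABL1 array), for Ebf1 between the sources (-0.21 after a median shift, -0.40 among GFP-negative arrays), for Irf4 (0.22) and Ighg3 (0.29) in the spleen with the mean of probe sets, and for the correlation of the GFP effects (r -0.0024, rho -0.036) without BCR-ABL1 GFP-negative replicate 1, where leaving out each array gave up to 0.0852 and 0.142. The Igll1 values without a spleen array belong to another probe set, picked anew in those fits. With fry, the NF-kB (adjusted p = 0.000723) and sex-linked lists (0.0221) had the opposite direction in the spleen. In the spleen, lists of mitosis, DNA replication and myeloid genes had medians of the same sign on all 3 scales.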

Other observations

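The genes named in this part were chosen after their values were seen.

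Some transcripts moved the same way with the reporter in both sources and were picked for that (n = 2 arrays against 2 in each), although genes higher in both were fewer than expected by chance (122 against 171) and genes lower in both more (128 against 88.3). Il2ra rose from 1274 to 3870.1 in BCR-ABL1 cells and from 624 to 1787 in the spleen, Oasl1 from 44.1 to 105 and from 851 to 2132, and Iigp1 from 119 to 450.3 and from 92.7 to 3971. Pla2g7 fell from 414 to 58.5 and from 2139 to 33.7, and Gja1 from 2165 to 299 and from 667 to the floor. The spleen falls of Pla2g7, Pygl and Gja1 go with those of the myeloid genes, so a shared direction there need not have a shared cause.

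When the 8 arrays were regrouped 4 against 4 with the cell source as a covariate, the split by reporter called 36 genes and the highest of the other splits 7, so 1 of 34 splits reached as many. These fits have no interaction term, so differences between the GFP effects add to their residual spread. Their counts lie under those of the main fit (8562 for the mean GFP effect, 9070 for the source). For the source, with the reporter as a covariate, the real split called 3943 genes and the highest other split 1036, again 1 of 34. Of these splits 32 part the arrays of a group, and since such arrays are alike, they were bound to call few genes. The 2 that keep each group together are too few for a share under 0.05. The other split with 1036 put BCR-ABL1 GFP-negative arrays with spleen GFP-positive arrays, so it points to the structure of the samples.

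The spleen GFP-positive arrays were close to the BCR-ABL1 arrays in cell cycle genes: Mki67 stood at 6414 there and at 7413 and 7139.9 in BCR-ABL1 fractions, against 1702 in spleen GFP-negative arrays. Vpreb1, Dntt and Rag1 kept the sources apart. Mouse sex went with the source: Xist and Eif2s3y never overlapped between sources, so female BCR-ABL1 and male spleen donors are a reading of the data that the labels do not give. Uty was at the floor in spleen GFP-negative arrays and at 213 ± 31.1 in GFP-positive ones, while Eif2s3y was high in both. The control 3' to 5' ratios were higher in spleen GFP-negative arrays (1.91 and 1.51 for a pair of housekeeping transcripts) than in the other groups (1.43 to 1.47 and 1.29 to 1.35).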
